A study of Mus musculus with 4 samples.

How the data were processed

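The series holds 4 single-cell RNA libraries, made by inDrops version 3 from cells of the central nervous system of C57BL6 mice. Per the labels, tissue was digested with papain, filtered at 70 µm and cleared on 30% Percoll, and TdTomato+ cells of Aldh1l1CreERT2-TdTomato mice were sorted by surface LAMP1 and TRAIL. The groups follow the sample labels: naive TRAIL-, naive TRAIL+, EAE TRAIL- and EAE TRAIL+, with 1 library each. The series description gives 3 naive and 3 EAE mice, and whether their cells were pooled in a library is not given in the sources used here. The authors' processing notes name Bowtie and the mouse genome GRCm38 for alignment. The version of Bowtie and the annotation are not given in the sources used here. The deposited tables hold a UMI count per barcode and gene, without scaling by the authors. The lowest total of a listed barcode was 100 UMIs, so the tables list only barcodes at or above that depth. The tables name genes by symbol alone, and 41343 of the 41862 gene columns (98.8%) match a symbol of the GENCODE annotation of GRCm38, from which gene positions were taken. The reporter transcript was not among the gene columns, so TdTomato was not measured.

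Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial counts. Of the barcodes left out, 1421 in naive TRAIL-, 1422 in naive TRAIL+, 1180 in EAE TRAIL- and 978 in EAE TRAIL+ were under 500 UMIs. More than 20% mitochondrial counts were found in 300, 177, 407 and 214 barcodes in the same order. Doublets were called per library with Scrublet in scanpy, at an expected rate of 5%, and 65 of 7868 barcodes were removed, 47 in naive TRAIL-, 7 in naive TRAIL+, 11 in EAE TRAIL- and 0 in EAE TRAIL+. Kept were 2206, 2219, 1574 and 1804 barcodes with 86.1%, 91.1%, 87.9% and 94.0% of the UMIs. The median mitochondrial share was 3.57%, 3.18%, 4.86% and 3.72%.

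For clustering, counts were scaled to 10000 per barcode and log-transformed. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 14 clusters. Each was named from marker lists of 16 cell types fixed before the data were examined. A cluster took the name of the list with most members among its 50 leading genes by fold. At least 3 of them had to be among its 100 leading genes, or 5 where fewer than 2 were among the first 10, and no other list could have more members among the first 10. A rule that markers must be seen in at least 20% of a cluster's cells was added after 1 cluster had been given an implausible name. One cluster of 26 barcodes, led by Fabp7, Npy, Frzb and Foxd3, met no name and stayed unnamed, and 3 barcodes with at least 20% haemoglobin counts were set apart as erythroid. The naming was tested on simulated data, in which 1303 of 1303 simulated cells had the class they were drawn from. These cells were drawn from the summed profiles of the classes already named, without free RNA or variation within a class. The result therefore does not show that the real clusters are rightly named.

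The plan was to compare astrocyte-like cells, if each library held at least 50 of them with 100000 UMIs. They numbered 181 in all, so the planned fallback to all kept barcodes was used for the main comparisons. Comparisons in microglia-like cells and in other classes were added after the data were seen. For microglia-like sums, cells with under 1% microglia marker counts were left out, a threshold set after 30 of 300 EAE TRAIL- cells had been found to carry few markers. It left out 4 cells in naive TRAIL-, 5 in naive TRAIL+, 30 in EAE TRAIL- and 9 in EAE TRAIL+.

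Counts were summed per library over the cells compared and divided by their total to give counts per 1000000 (CPM). A ratio of CPM between 2 libraries was given with an exact Clopper-Pearson 95% interval, a level with an exact Poisson interval and a share of cells with an exact Clopper-Pearson interval. These cover counting error only and not the difference between animals, which 1 library per group does not measure; no p-value was computed and no replicate check was possible. They also take UMIs as independent, so where few cells carried Tnfsf10, intervals from 2000 resamplings of whole cells were added after the values were seen. No such interval was computed for monocyte- or macrophage-like cells. Where a library had no count, a floor of 3 counts stood in its place and the fold was given as at least that size. Genes with a mean of at least 50 CPM were compared (a higher floor in classes with few counts), and those at least 2-fold apart were counted. The shares of cells with a UMI were computed after thinning every cell to 500 UMIs.

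For 23 gene lists and the marker lists of 16 cell types fixed before the data were examined, members with a mean of at least 10 CPM were called higher or lower at 1.5-fold and otherwise between. The median log2 ratio was placed among 10000 random lists matched in 20 bins of expression. That position describes these libraries and is not a test across animals. Lists with under 5 measured members were not scored.

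Genes were named by a rule set before the data were examined. Mitochondrial, ribosomal and predicted genes and the markers of cell types other than astrocytes were left out. Of the others at or above 50 CPM, the 12 highest and 12 lowest were named in EAE TRAIL+ against EAE TRAIL- and in EAE against naive TRAIL+, and 6 each way elsewhere, ranked by the interval bound nearest to 1. Tnfsf10, Lamp1, Aldh1l1 and Gfap were always named, as were the members with the highest mean CPM of each list described. In microglia-like and other class-level comparisons the rule was the same. Xist, Ddx3y and the genes that lead clusters were chosen after their values were seen where the rule did not name them. Some genes that the rule names are not reported here.

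The pipeline was tested on simulated data for each comparison, with 200 genes changed by 1.5- to 8-fold. Over all kept barcodes, 3669 genes were simulated for TRAIL+ against TRAIL- in EAE, 3848 in naive, 3320 for EAE against naive in TRAIL+ and 4079 in TRAIL-. At least 2-fold apart were 44%, 54%, 58% and 54% of genes changed 2-fold, 100% of genes changed 4-fold and 0% of unchanged genes. In microglia-like cells, with 3189, 3178, 3214 and 3225 genes simulated, 50%, 44%, 50% and 60% of genes changed 2-fold passed, as did 0.0335%, 0.168%, 0% and 0.496% of unchanged genes. The simulated counts were Poisson draws per library, without spread between cells or animals. These rates therefore cover counting error only and do not give the rate of false differences in the real libraries.

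The alternatives tried were edgeR's TMM factors, DESeq2 size factors, a total without mitochondrial, ribosomal and Malat1 counts, the mean of the cells' CPM, floors of 20 and 100 CPM, minimum depths of 300 and 1000 UMIs, a 10% mitochondrial limit, doublets kept, Leiden resolutions of 0.5 and 2 for class shares, thinning to 1000 UMIs or none, and astrocyte-like cells alone. The same alternatives on microglia-like cells, and sums over every cell of that class or without the cluster led by immune genes, were added after the data were seen. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.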

Results

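Single-cell RNA was captured by inDrops, a droplet method that tags each RNA molecule with a unique molecular identifier (UMI), from the central nervous system of C57BL6 mice that carried the Aldh1l1CreERT2-TdTomato reporter of astrocytes. TdTomato+ cells were sorted, and cells positive for surface LAMP1 were then split into TRAIL+ and TRAIL- fractions. TRAIL is the death ligand encoded by Tnfsf10, and LAMP1 is a lysosomal membrane protein that reaches the cell surface when lysosomes fuse with the plasma membrane. The mice were either naive or at the peak of experimental autoimmune encephalomyelitis (EAE), the mouse model of multiple sclerosis induced with MOG peptide. The series description gives 3 naive and 3 EAE mice, and there was 1 library for each of the 4 groups. No spread between animals could therefore be measured, and every interval given here covers counting error only, or the spread between cells where cells were resampled.

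The deposited tables listed 3703 barcodes for naive TRAIL-, 3673 for naive TRAIL+, 2808 for EAE TRAIL- and 2803 for EAE TRAIL+. The total counts ranged from 2856696 UMIs in EAE TRAIL- to 3984975 in EAE TRAIL+. After filtering, 7803 of the 12987 barcodes were kept. Median depth per kept barcode was 947 UMIs in naive TRAIL-, 1504 in naive TRAIL+, 1188 in EAE TRAIL- and 1914.5 in EAE TRAIL+.

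The purpose given in the title is the transcriptional profile of TRAIL+LAMP1+ astrocytes beside that of LAMP1+ astrocytes in EAE. In the TdTomato+ LAMP1+ sort, however, barcodes with an astrocyte profile were a small part of every library. They made up 1.54% (exact binomial 95% interval 1.07 to 2.15) of kept barcodes in naive TRAIL-, 6.13% (5.17 to 7.21) in naive TRAIL+, 0.191% (0.0393 to 0.556) in EAE TRAIL- and 0.443% (0.192 to 0.872) in EAE TRAIL+. Microglia-like barcodes, with Csf1r, C1qb and C1qc among their markers, made up 85.1% (83.6 to 86.6) of naive TRAIL+ and 90.1% (88.6 to 91.4) of EAE TRAIL+. Their share was 14.3% (12.8 to 15.8) in naive TRAIL- and 19.1% (17.1 to 21.1) in EAE TRAIL-. The TRAIL- libraries held mostly vascular cells. Endothelial-like barcodes, marked by Flt1 and Cldn5, were 51.8% of naive TRAIL- and 31.5% of EAE TRAIL-, against 2.43% and 0.166% in the TRAIL+ libraries. Pericyte or smooth muscle barcodes, marked by Rgs5 and Vtn, were 22.6% of naive TRAIL- and 29.2% of EAE TRAIL-. Monocyte or macrophage barcodes were more frequent in EAE, with 14.5% against 0.997% in TRAIL- and 8.65% against 3.61% in TRAIL+. The class joins a cluster led by Chil3 and Plac8, with 139 barcodes in EAE TRAIL+ against 24 in naive TRAIL+, and a macrophage cluster led by Pf4 and Mrc1, with 17 against 56.

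**Figure D1:**
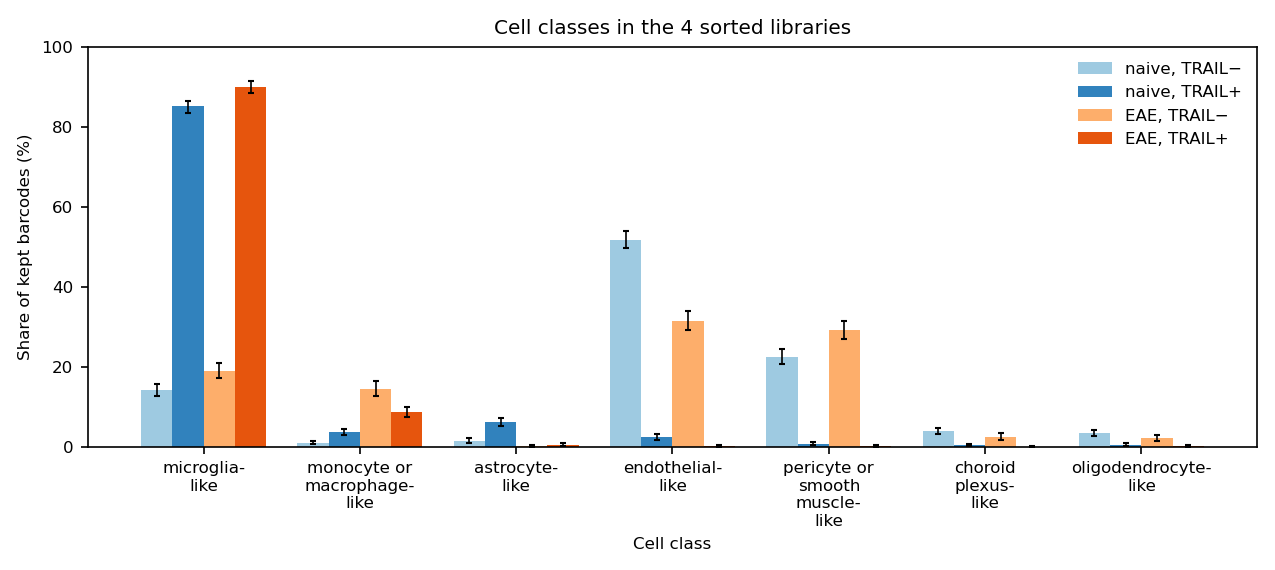
Share of kept barcodes (y axis, percent) assigned to each of 7 cell classes (x axis) in the 4 libraries; bars are shares and error bars are exact binomial 95% intervals covering counting error only. Microglia-like barcodes reach 85.1% and 90.1% in the TRAIL+ libraries, and endothelial-like barcodes reach 51.8% and 31.5% in the TRAIL- libraries.

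The astrocyte-like class held 34, 136, 3 and 8 cells in naive TRAIL-, naive TRAIL+, EAE TRAIL- and EAE TRAIL+. Only naive TRAIL+ met the minimum planned for comparisons in that class. The comparisons of whole libraries that follow use all kept barcodes. They contrast sorted fractions of mixed makeup, and a difference there can lie in which cells were captured as well as in expression within a cell type.

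The sort genes themselves were measured first. Tnfsf10 (chromosome 3, 27317028 to 27342427, GRCm38) was lower, not higher, in the fraction sorted as TRAIL+. In naive mice it stood at 4.43 counts per 1000000 UMIs (CPM; Poisson 95% interval 2.53 to 7.19) in TRAIL+ and 102 CPM (90.3 to 115) in TRAIL-, a 23.04-fold lower level (13.9 to 40.9). In EAE the levels were 17.4 CPM (13.4 to 22.1) and 49.0 CPM (40.7 to 58.5), 2.82-fold lower in TRAIL+ (2.07 to 3.88). Between disease states Tnfsf10 was 3.92-fold higher (2.24 to 7.26) in EAE than naive TRAIL+ and 2.08-fold lower (1.68 to 2.60) in EAE than naive TRAIL-. Endothelial-like cells gave 95.2% of the Tnfsf10 UMIs in naive TRAIL- and 81.3% in EAE TRAIL-, at 238 CPM in naive TRAIL- and 181 CPM in EAE TRAIL-. After every barcode was thinned to 500 UMIs, 6.04% (4.73 to 7.58) of endothelial-like cells in naive TRAIL- had a Tnfsf10 UMI. The same share was 0.402% in pericyte-like cells of that library, whose median depth before thinning was 791 UMIs against 894 in endothelial-like cells. In microglia-like cells Tnfsf10 was 4.14-fold lower (1.66 to 9.85) in naive TRAIL+ than naive TRAIL-, 2.17-fold lower (1.23 to 3.68) in EAE TRAIL+ than EAE TRAIL-, and 3.44-fold higher (1.91 to 6.56) in EAE than naive TRAIL+. Few cells carried these UMIs: 10 UMIs in 3 of 311 cells in naive TRAIL-, 15 in 11 of 1884 in naive TRAIL+, 20 in 8 of 270 in EAE TRAIL- and 54 in 33 of 1616 in EAE TRAIL+. The shares of cells, not thinned, overlapped between the fractions, at 0.965% (0.199 to 2.79) in naive TRAIL- against 0.584% (0.292 to 1.04) in naive TRAIL+, and at 2.96% (1.29 to 5.75) in EAE TRAIL- against 2.04% (1.41 to 2.86) in EAE TRAIL+. With whole cells resampled, the interval of the fold was 0 to 15.5 in naive mice and 0.409 to 5.43 in EAE, so neither difference between the fractions in microglia-like cells is settled, while that of EAE over naive TRAIL+ was 1.65 to 9.06. With the microglial cluster led by immune genes left out, the EAE log2 ratio was 0.70 (-1.28 to 3.81), with 2 Tnfsf10 UMIs in TRAIL-, so its direction rests on that cluster. In monocyte- or macrophage-like cells of EAE, Tnfsf10 was at 25.8 CPM in TRAIL+ against 1.63 CPM in TRAIL-, a 15.8-fold ratio on few counts (2.30 to 681). Its UMIs lay in 4 of 156 TRAIL+ cells and 1 of 229 TRAIL- cells. These shares, not thinned, overlapped at 2.56% (0.703 to 6.43) and 0.437% (0.0111 to 2.41). Whole cells were not resampled here, so this difference is not settled either. No Tnfsf10 UMI was found in astrocyte-like cells, at 0 of 136 in naive TRAIL+ and 0 of 34 in naive TRAIL-. A limit of 3 counts of the total puts the share of cells with a UMI at this depth at 2.21% and 8.82%. The exact 95% intervals reach 2.68% and 10.3%. These limits do not apply to the share of cells that express the gene.

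Lamp1 (chromosome 8, 13159161 to 13175338) was broadly detected. It was 1.44-fold higher (1.35 to 1.54) in naive TRAIL+ than naive TRAIL-, at 744 against 516 CPM, and near equal in the EAE fractions at 678 and 663 CPM. At 500 UMIs per cell, 27.5% of barcodes in naive TRAIL+ and 19.0% in naive TRAIL- had a Lamp1 UMI, against 12.9% in endothelial-like cells of naive TRAIL-. Aldh1l1 (chromosome 6, 90486427 to 90600203), whose promoter drives the reporter, was at 7.85 and 10.8 CPM in naive TRAIL- and TRAIL+ and 4.38 and 5.61 CPM in EAE TRAIL- and TRAIL+. Within naive astrocyte-like cells it reached 87.6 CPM in TRAIL- and 145 CPM in TRAIL+. Gfap (chromosome 11, 102887336 to 102900912), the astrocyte filament gene, was at or below 4.71 CPM in every library and at 50.03 and 67.2 CPM in naive astrocyte-like cells of TRAIL- and TRAIL+.

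**Figure D2:**
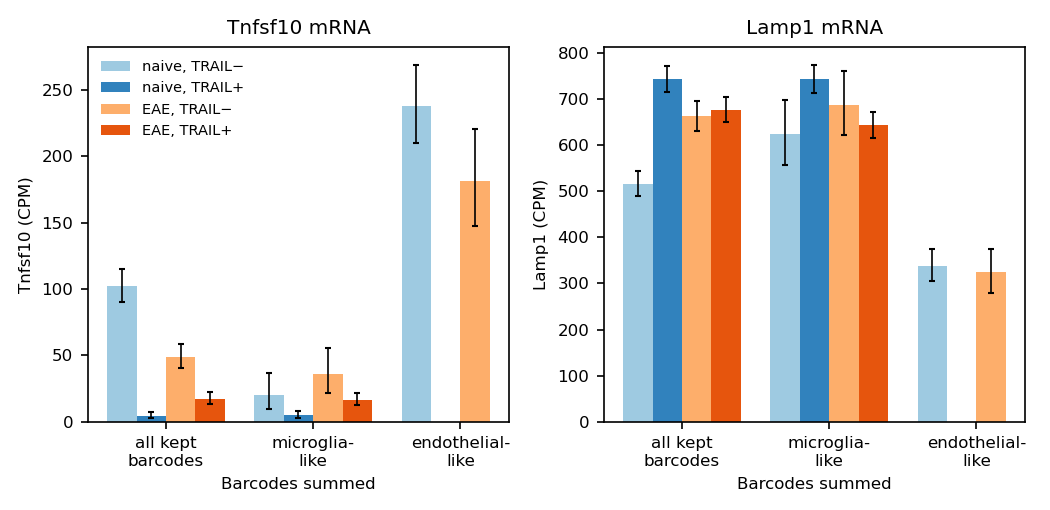
Level of Tnfsf10 and Lamp1 (y axes, CPM) in all kept barcodes, microglia-like cells and endothelial-like cells of the 4 libraries (x axis); bars are the summed counts scaled to CPM and error bars are Poisson 95% intervals covering counting error only. Endothelial-like cells are drawn for the TRAIL- libraries alone, where Tnfsf10 is at 238 and 181 CPM, against 4.43 and 17.4 CPM in all barcodes of the TRAIL+ libraries.

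Which genes distinguish the TRAIL+ from the TRAIL- fraction in EAE was the study's central comparison. Over all kept barcodes, 427 genes were at least 2-fold higher and 631 at least 2-fold lower in EAE TRAIL+ among 3669 genes compared. With TMM scaling, which moved the median of all genes by 0.10 (log2), the split was 497 higher and 560 lower, and DESeq2 size factors moved it by 0.12. Among the genes named, P2ry13, an ADP receptor of microglia, was 5.82-fold higher (5.05 to 6.74), the fructose transporter gene Slc2a5 5.61-fold, Ptgs1 5.31-fold and the lens-type crystallin Crybb1, also a microglial gene, 5.05-fold. The inhibitory checkpoint gene Vsir was 4.43-fold higher, and the B-lineage and myeloid transcription factor gene Pou2f2 4.65-fold. The inflammatory mediators Ccl3, a chemokine for monocytes and T cells, and Tnf were 4.31-fold (4.13 to 4.50) and 4.18-fold (3.98 to 4.39) higher, at 4251 and 3055 CPM in TRAIL+. Tagap, Ltc4s, Fgd2 and Hpgds, all expressed in leukocytes, were 5.73-, 5.11-, 4.63- and 4.36-fold higher.

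Among the named genes lower in EAE TRAIL+, Mgp, an inhibitor of vessel calcification, was 494-fold lower (250 to 1150), Igfbp7 150-fold (116 to 199) and the mural chemokine gene Cxcl12 143-fold (91.4 to 238). The endothelial transcription factor gene Sox18 was 682-fold lower on few TRAIL+ counts (122 to 26998), and Foxf2, a transcription factor gene of brain pericytes, was 179-fold lower. Adgrl4, Tm4sf1, Ccn1, Spock2 and the collagen chaperone gene Serpinh1 were 159-, 136-, 196-, 125- and 306-fold lower. The gap-junction gene Gjc1 was 315-fold and the FOXO-target gene Depp1 396-fold lower.

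Microglia markers were a median 4.23-fold higher in TRAIL+, with all 15 members at least 1.5-fold higher. Endothelial markers were a median 86.0-fold lower (Flt1 86.9-fold, Cldn5 263-fold) and pericyte markers 168-fold lower (Rgs5 168-fold). Of 22 NF-kB targets, 11 were at least 1.5-fold higher, led by Nfkbia at 2.86-fold and Tnfaip3 at 3.96-fold, and 4 were lower. The lysosome list, which the LAMP1 sort made of interest, had 12 of 26 members higher and none lower, with a median log2 ratio above 99.4% of random lists matched for expression. Of 22 type I interferon-stimulated genes, 15 were lower and none was higher, and oxidative phosphorylation genes were lower in 20 of 23. Pan-reactive astrocyte genes were lower in 9 of 10, including Vim at 4.91-fold, Hspb1 at 17.0-fold and Cd44 at 4.29-fold, all of them also expressed outside astrocytes. MHC class II genes differed little, with 3 of 8 members higher and 5 between. Death ligand and receptor genes, the pathway of TRAIL itself, were higher in 3 of 15, lower in 3 and between in 9. Glycolysis genes were lower in 11 of 15, with the glucose transporter gene Slc2a1 of the blood-brain barrier 10.4-fold lower and Hk2 2.21-fold higher, and cholesterol synthesis genes were lower in 12 of 17. Immediate early genes, which tissue digestion can induce, were higher in 11 of 20. Unfolded protein response genes were higher in 5 of 19, among them the chaperone gene Hspa5 at 1.80-fold, and lower in none.

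In naive mice the same contrast asked what marks the TRAIL+ fraction without disease. Among 3848 genes, 565 were at least 2-fold higher and 875 at least 2-fold lower in naive TRAIL+, and with TMM, which moved the median by 0.16 (log2), 667 and 714. DESeq2 size factors moved it by 0.11. Lag3, an inhibitory receptor of lymphocytes also found in microglia, was 7.73-fold higher (5.82 to 10.4), the endolysosomal exonuclease gene Pld4 6.20-fold and the haematopoietic adaptor gene Hcls1 6.95-fold. Ccl3 was 5.66-fold (5.38 to 5.96), Ccl4 5.31-fold (5.14 to 5.49) and the lysosomal protease gene Ctss 5.39-fold (5.14 to 5.66) higher. Among 26 lysosome genes 18 were higher, including the proteases Ctsb at 3.46-fold, Ctsd at 3.91-fold and Lgmn at 4.03-fold. NF-kB targets were higher in 14 of 19, with Tnf at 4.86-fold and Nfkbiz at 3.91-fold. In astrocyte-like cells alone Lag3 and Hcls1 had 5 and 4 UMIs in TRAIL+ and 0 in TRAIL-, too few to give a direction.

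Capillary and mural genes were lower in naive TRAIL+. The pericyte ATPase gene Atp13a5 was 66.2-fold lower (41.1 to 114), the smooth muscle calcium-binding gene Casq2 76.1-fold, Ndufa4l2 55.2-fold, Depp1 51.7-fold, P2ry14 50.7-fold and the capillary carbonic anhydrase gene Car4 41.0-fold (31.0 to 55.3). Endothelial markers were a median 25-fold and pericyte markers 32.3-fold lower. Type I interferon-stimulated genes were lower in 14 of 19, with Ifitm3 10.3-fold and Ifi27 3.63-fold lower. Astrocyte markers were at least 1.5-fold higher in 14 of 23, for example the glutamate transporter gene Slc1a3 at 2.31-fold, and lower in 3, but their summed level was 5933 CPM in naive TRAIL+ against 6486 CPM in naive TRAIL-.

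Disease was compared within each sorted fraction. In TRAIL+, 116 genes were at least 2-fold higher and 63 at least 2-fold lower in EAE than naive among 3320. The MHC class II genes H2-Ab1, Cd74 and H2-Aa were 9.96-, 8.97- (8.47 to 9.50) and 8.48-fold higher, and 7 of 8 members of the class II list were higher. Gbp2 and Iigp1, interferon-induced GTPase genes, were 20.2-fold (14.7 to 28.7) and 15.6-fold higher. The T-cell chemokine gene Ccl5 was 29.0-fold (18.8 to 47.1), the Fc receptor gene Fcgr4 15.7-fold and the adhesion genes Cd44 and Thbs1 12.9- and 10.3-fold higher. Lgals3 and Spp1, genes of activated phagocytes, were 21.9- and 8.37-fold higher. Of 19 type I interferon-stimulated genes 18 were higher, among them Isg15 at 5.67-fold and Bst2 at 2.78-fold, and 13 of 16 MHC class I genes were higher, H2-K1 by 2.81-fold and H2-D1 by 3.23-fold.

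Astrocyte and radial glial genes were lower in EAE TRAIL+. Fabp7, a brain lipid-binding protein gene, was 112-fold lower (47.6 to 346), Gpr37l1 20.1-fold, the gap-junction gene Gja1 20.05-fold, Cpe 19.8-fold, the perineuronal proteoglycan gene Bcan 16.8-fold, Id4 16.6-fold, Ptn 14.9-fold and Plpp3 13.2-fold (10.9 to 16.2). Prnp, Htra1 and Sparcl1 were 15.9-, 14.7- and 11.0-fold lower. All 23 measured astrocyte markers were lower, by a median of 9.68-fold, as were 19 of 22 astrocyte homeostasis genes. The astrocyte-like share was 6.13% in naive TRAIL+ and 0.443% in EAE TRAIL+, so the whole-library level of these genes does not give their level per astrocyte. Fabp7 also leads an unnamed cluster that held 20 barcodes in naive TRAIL+ and 0 in EAE TRAIL+. The complement genes C4b and C3 were 15.8- and 8.68-fold higher and Clu was 10.4-fold lower. Of 6 neutrophil markers measured 4 were lower, S100a9 by 227-fold (88.3 to 834) and S100a8 by 44.7-fold (26.4 to 82.2), while the 11 listed markers summed to 367 CPM in EAE and 1014 CPM in naive TRAIL+. In microglia-like cells that sum was 379 CPM in EAE TRAIL+ and 376 CPM in naive TRAIL+, so the difference lay in other barcodes. No cluster was named neutrophil, and whole cells were not resampled for these genes.

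In TRAIL- the comparison of EAE with naive gave 285 genes at least 2-fold higher and 220 at least 2-fold lower among 4079. The interferon gamma-induced chemokine gene Cxcl9 was at least 397-fold higher, at 445 CPM against no count in naive TRAIL-, the lectin gene Clec4d 421-fold (75.1 to 16674) and Ccl5 248-fold (68.4 to 2057). Il1rn, the interleukin-1 receptor antagonist gene, was 78.7-fold (49.6 to 133) and AA467197, a gene of activated macrophages, 106-fold higher. Monocyte markers were a median 10.1-fold higher, with Plac8 at 27.0-fold, Chil3 at 28.4-fold and Lyz2 at 7.20-fold, next to the larger monocyte share of that library. All 8 MHC class II genes were higher, as were 28 of 33 interferon gamma response genes and 15 of 26 lysosome genes. Il1b was 4.30-fold higher. The immediate early genes Fos and Jun were 2.08- and 2.30-fold lower. Among the named genes lower in EAE were the astrocyte genes Gpr37l1 by 20.4-fold (11.95 to 37.7), Id4 by 5.90-fold, Gpm6a by 5.78-fold and Aldoc by 5.04-fold. Rflnb, a filamin-binding gene, was 4.79-fold lower. The 25 listed astrocyte markers differed less in sum, at 4403 CPM in EAE and 6486 CPM in naive TRAIL-. Endothelial markers were a median 2.13-fold lower, while pericyte markers lay between in 9 of 10. Erythroid markers were 19.2-fold higher.

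EAE and naive libraries also differed in sex-linked genes. Xist (chromosome X, 103460366 to 103483254), expressed from the inactive X chromosome of females, was 117-fold higher (83.5 to 169) in EAE than naive TRAIL+ and 61.9-fold higher (42.9 to 92.7) in TRAIL-. Ddx3y, on the Y chromosome, was 47.6-fold and 33.4-fold lower. Disease and sex of the mice therefore cannot be separated in any comparison of EAE with naive.

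Microglia-like cells were the 1 class with at least 270 cells in every library, and comparisons within it reduce, but do not remove, the difference in cell makeup. They were chosen after the data were seen. The sums held 311 cells in naive TRAIL-, 1884 in naive TRAIL+, 270 in EAE TRAIL- and 1616 in EAE TRAIL+. Most naive cells lay in 2 clusters, while another cluster, led by the immune genes Hcar2, H2-Q7, Ccl12, Tnf and Cd74, held 163 of the EAE TRAIL- cells and 646 of the EAE TRAIL+ cells summed. This immune-gene cluster had 0 microglia markers among its 10 leading genes and 9 among its 100. The other 2 had 7 and 5 among the first 10, so its name as microglia-like is less certain.

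Within microglia-like cells of the TRAIL+ libraries, 79 genes were at least 2-fold higher and 12 at least 2-fold lower in EAE than naive among 3214. MHC class II genes led. H2-Aa was at 1175 CPM against 13.5 CPM, 87.0-fold higher (64.2 to 121), H2-Eb1 was 64.0-fold, H2-Ab1 42.5-fold and the invariant chain gene Cd74 24.7-fold (21.98 to 27.8) higher. Interferon-induced genes followed, with the GTPase genes Iigp1 and Gbp2 34.2- and 20.03-fold, the antiviral gene Ifitm3 14.5-fold, Ifi27l2a 9.77-fold and Isg15 7.91-fold higher. Fcgr4, Ly6a and the immunoregulatory gene Fgl2 were 12.6-, 12.3- and 8.03-fold higher. The lower genes differed by smaller ratios. Fscn1, an actin-bundling gene of homeostatic microglia, was 2.32-fold lower (2.18 to 2.48), Hpgd 2.27-fold, Papss1 2.47-fold, the lysosomal sulfatase gene Arsb 2.24-fold and Cst3, a cysteine protease inhibitor gene, 1.89-fold (1.87 to 1.91). Fam102b, Cmtm6, Marcksl1 and Sparc were 2.19-, 2.02-, 1.996- and 1.84-fold lower, and the growth-control genes Jund and Btg2 2.04- and 1.87-fold.

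The class II list was a median 17.2-fold higher in EAE TRAIL+ microglia-like cells, with 7 of 8 members higher. Type I interferon-stimulated genes were higher in 18 of 19, interferon gamma response genes in 25 of 33 and MHC class I genes in 13 of 16, while monocyte markers had a median log2 ratio of -0.06 and microglia markers of -0.18. Erythroid markers were also higher in these cells, at 176 CPM in EAE and 11.6 CPM in naive, so blood RNA differed between the sums. With the immune-gene cluster left out, the class II median was 2.21 (log2) against 4.11, and the log2 ratio of H2-Aa was 3.70. In the TRAIL- libraries H2-Aa was 482-fold (133 to 3983), H2-Eb1 127-fold (49.2 to 466) and Cd74 37.1-fold (27.2 to 52.2) higher in EAE, and the NADPH oxidase gene Cybb was 89.1-fold higher on few naive counts (15.6 to 3550). H2-Ab1 was at least 58.2-fold higher, but with the immune-gene cluster left out it had 1 UMI in EAE TRAIL- and 0 in naive TRAIL-, which gives no direction. The class II list was a median 15.7-fold higher, and 17 of 19 type I interferon-stimulated genes were higher, with Ifitm3 at 10.5-fold. Fos and Jun were 2.80- and 2.86-fold lower. The signalling gene Mtss1, the activin receptor gene Acvr1, Herpud2, Sde2 and the ion transporter gene Slc12a2 were 7.94-, 6.22-, 5.63-, 5.36- and 4.39-fold lower. Of 3225 genes, 239 were at least 2-fold higher and 277 lower, and 294 and 204 with TMM. Monocyte markers were also higher in these TRAIL- cells, with a median log2 ratio of 1.69.

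**Figure D3:**
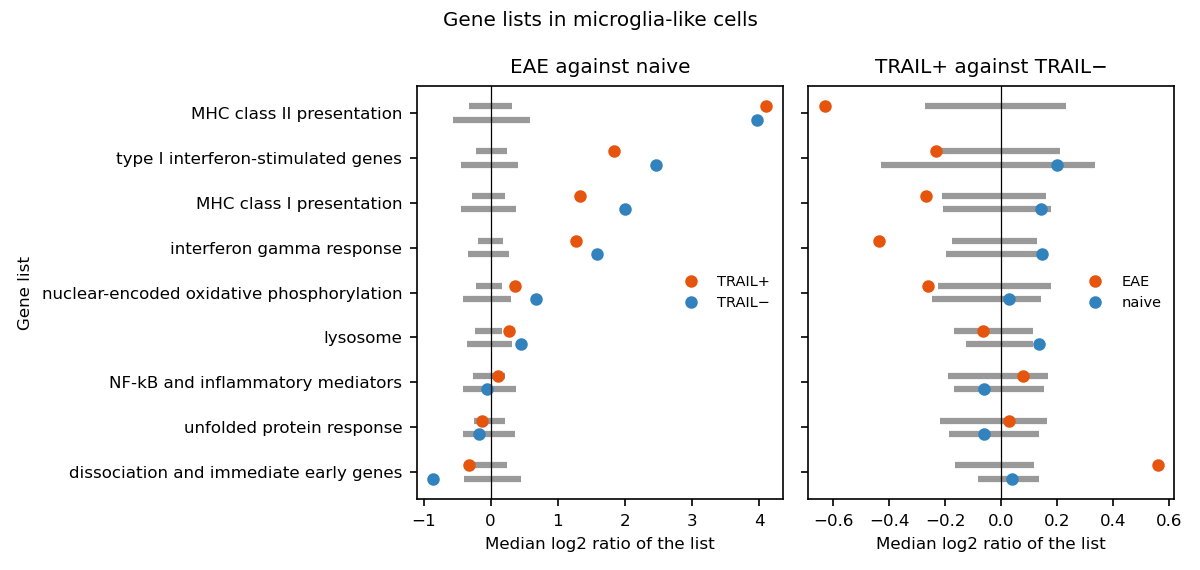
Median log2 ratio (x axis) of 9 gene lists (y axis) in microglia-like cells, for EAE against naive on the left and TRAIL+ against TRAIL- on the right; dots are medians and grey bars the central 95% of 10000 random lists matched for expression. MHC class II presentation has the highest medians for EAE against naive, at 4.11 in TRAIL+ and 3.97 in TRAIL-, and is below the random lists at -0.63 for EAE TRAIL+ against TRAIL-.

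Microglia-like cells of the TRAIL+ and TRAIL- gates were compared last. In EAE, 24 genes were at least 2-fold higher and 50 at least 2-fold lower in TRAIL+ among 3189, where counting error alone would give 1.58. The immune-gene cluster held 163 of 270 TRAIL- cells and 646 of 1616 TRAIL+ cells, so the fractions also differed in the mix of clusters. Without it 107 TRAIL- cells remained, and the number that counting error alone would give in this smaller set was not computed. There 113 genes were higher and 180 lower, and 39 of the 74 genes were shared. The split depended on the expression floor, with 195 higher and 192 lower at 20 CPM. Among the genes higher in TRAIL+ were the antiproliferative gene Tob1 by 4.71-fold (2.66 to 9.22), the MAP kinase phosphatase gene Dusp6 by 2.32-fold, the chaperone gene Hspa1a by 1.97-fold (1.77 to 2.20), Hspa1b by 1.79-fold, Fos by 1.76-fold (1.65 to 1.87) and Egr1 by 1.71-fold. Txnip and Cited2 were 1.94- and 1.95-fold higher, Sdc4 2.27-fold, Sox4 2.61-fold and Tbc1d9b 2.78-fold. Immediate early genes were at least 1.5-fold higher in 10 of 20 and lower in none. Among the genes lower in TRAIL+, the hyaluronan receptor gene Cd44 was 5.97-fold lower (3.94 to 9.04), the filament gene Vim 3.52-fold, Il1rn 3.397-fold, Txn1 3.31-fold, Rab7b 3.22-fold and Acod1, the itaconate enzyme gene, 2.83-fold. The interferon-induced genes Ly6a, Iigp1 and Ifi207 were 2.5-, 2.45- and 2.45-fold lower, and the nuclear genes Lmnb1, Rfc1 and Gtf2h1 2.99-, 2.96- and 2.77-fold. H2-Aa and H2-Eb1 were 1.64- and 1.70-fold lower and Cd74 1.27-fold lower. Interferon gamma response genes were lower in 8 of 33 and higher in 1. Endothelial markers were a median 6.69-fold lower in the TRAIL+ cells, so vascular transcripts differed between these sums as well. Cd44 and Il1rn also lead the monocyte cluster of Chil3, Plac8 and Arg1. In TRAIL- against TRAIL+, Chil3 was at 16.2 against 6.45 CPM and Plac8 at 37.8 against 14.7 CPM, but Arg1 at 0 against 3.69 CPM. The summed monocyte or macrophage markers were at 2314 against 2122 CPM. A part of monocyte RNA in the Cd44 and Il1rn ratios was not tested.

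In naive mice the microglia-like cells of the 2 fractions were more alike. Of 3178 genes, 11 were at least 2-fold higher and 26 at least 2-fold lower in TRAIL+, with 2.45 expected from counting error alone, and 15 and 17 with TMM. Apoe, a lipid transport gene of activated microglia, was 2.92-fold higher (2.31 to 3.75), the p53 regulator gene Mdm2 2.98-fold, Gbp7 2.24-fold, H2-DMb1 2.15-fold and the pseudogene Ftl1-ps1 1.58-fold. Lyz2 was 1.98-fold higher. Ttc9c, Pdpk1, Cdc123, Ktn1 and the Polycomb gene Suz12 were 3.01-, 2.5-, 2.58-, 2.38- and 2.38-fold lower. Immediate early genes lay between in 19 of 20 and lysosome genes in 25 of 26. Endothelial markers were a median 12.8-fold lower in the TRAIL+ cells, with Cldn5 at 12.4-fold and Itm2a at 34.2-fold lower.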

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

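All tests and explanations weighed in this part were chosen only after the results they concern were seen.

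Some genes differed between TRAIL+ and TRAIL- in opposite directions in EAE and naive mice, and the difference was not tested, since each group had 1 library. They were drawn only from genes that had been named in these same libraries. Required were a ratio of at least 1.5-fold and an interval clear of 1 in both states, and more than 3 UMIs in every library. Values are the log2 ratio in EAE minus that in naive. Over all kept barcodes, Fabp7 differed by -4.30, at 149 CPM in naive TRAIL+ and 76.6 in naive TRAIL- but 1.33 in EAE TRAIL+ and 13.5 in EAE TRAIL-. Il1rn differed by -3.32, at 22.4 against 6.73 CPM in naive mice and 177 against 529 CPM in EAE. Plpp3 differed by -2.62, at 385 against 221 CPM and then 29.1 against 102 CPM. For these whole-library values, cell makeup was not separated from expression. In naive TRAIL-, naive TRAIL+, EAE TRAIL- and EAE TRAIL+, the unnamed cluster led by Fabp7 held 5, 20, 1 and 0 barcodes. The cluster led by Chil3, with Il1rn among its 10 leading genes, held 20, 24, 228 and 139. Astrocyte-like cells, with Plpp3 among their listed markers, numbered 34, 136, 3 and 8. In microglia-like cells Apoe differed by -2.45, at 427 against 146 CPM in naive mice and 1299 against 2434 CPM in EAE. The opposite order, lower in TRAIL+ in naive mice and higher in EAE, was found for 6 genes, each highest in naive TRAIL-. All 6 had been named for a low ratio against naive TRAIL-, which favours a high value there. Their EAE TRAIL- values rest on 7 UMIs (Mtss1) to 38 UMIs (Slc12a2). Ttc9c differed by 2.56, at 41.8 against 126 CPM in naive mice and 45.8 against 23.4 CPM in EAE. Mtss1 differed by 2.20, at 60.2 against 99.9 CPM and 34.7 against 12.6 CPM. Sde2 differed by 2.03, at 92.0 against 164 CPM and 70.1 against 30.6 CPM. Suz12 differed by 2.001, at 42.8 against 102 CPM and 54.4 against 32.4 CPM. Herpud2 differed by 1.84, at 91.7 against 152 CPM and 58.4 against 27.0 CPM. Slc12a2 differed by 1.68, at 176 against 299.8 CPM and 129 against 68.3 CPM.

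The first pattern weighed was that the TRAIL+ fractions of an astrocyte sort held mostly microglia-like barcodes. Were these barcodes other cells with free microglial RNA, they would keep markers of their own class. They carried the markers of the non-myeloid classes at 4.81% (4.66 to 4.96) of the level in those classes in naive TRAIL+. In EAE TRAIL+, where those classes held 22 barcodes, it was 2.28% (2.18 to 2.39). The clusters were named from the same marker lists, which favours a low level, so the test cannot exclude free RNA. Loss of astrocytes to the barcode filter would leave astrocyte RNA in the barcodes left out, but these carried astrocyte markers at 15.7% (14.9 to 16.5) and 7.14% (6.27 to 8.14) of the level in astrocyte-like cells, which argues against it as the whole cause. A partial loss stays open, since their astrocyte marker level was 10297 CPM in naive TRAIL+ and 4512 CPM in EAE TRAIL+, against 5933 and 1694 CPM in kept barcodes. An exchange of the TRAIL labels would give lower Tnfsf10 in the libraries named TRAIL+, and Tnfsf10 was 23.04-fold lower in naive and 2.82-fold lower in EAE. That also follows if surface protein and mRNA differ, so the exchange stays open. An astrocyte reporter, antibody or gate that also passes microglia was not tested, since neither reporter RNA nor sort data were used here.

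The second pattern was lower Tnfsf10 mRNA in TRAIL+. Had the naive fractions differed only in cell class makeup, naive TRAIL+ would be at 20.9 CPM, against 4.43 CPM measured. The computed level rests on 10 UMIs in 3 microglia-like cells, and with whole cells resampled its interval, 3.96 to 47.8, overlaps that of the measured level, 1.94 to 7.51, so makeup stays open. In EAE the computed 30.8 CPM (6.73 to 63.3) overlaps the 17.4 CPM (10.9 to 24.1) measured, and makeup stays open there too. Endothelial RNA inside microglia-like barcodes of TRAIL- would carry Tnfsf10 in the endothelial ratio, 7.50 Tnfsf10 UMIs per 1000 endothelial marker UMIs in naive and 6.56 in EAE. The microglia-like barcodes had 59.5 (0 to 158 with whole cells resampled) and 160 (28.6 to 400), on 10 UMIs in 3 cells and 20 UMIs in 8 cells. The naive interval includes the endothelial ratio and only the EAE interval lies above it. However, the 3 and 8 cells with these UMIs held 4 and 11 endothelial marker UMIs. Endothelial-like cells with a Tnfsf10 UMI held 3324 endothelial marker UMIs beside 260 of Tnfsf10 in naive TRAIL-, and 1191 beside 100 in EAE TRAIL-. These values argue against endothelial RNA as the source of Tnfsf10 in these few cells. A biological explanation, uptake of TRAIL protein or regulation after transcription, was not tested because no protein was measured here.

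The third pattern was the higher MHC class II level in EAE microglia-like cells. Monocyte RNA would bring monocyte markers, and their median log2 ratio was 1.69 in TRAIL- and -0.06 in TRAIL+. Their summed excess, however, was 1.42% of what the Cd74 excess would need in TRAIL- and -7.65% in TRAIL+. The Cd74 excess would need a monocyte share of 54.1% in TRAIL- and 20.9% in TRAIL+, and no single marker gave more than 8.10% and 6.48%. In TRAIL+ the sum was pulled down by Itgam, at 823 CPM in EAE against 1066 in naive, and Cd14, at 628 against 871. Above naive were 8 of 12 markers in TRAIL- and 10 of 15 in TRAIL+. The clusters were named from the same marker lists, which favours a low excess. Some monocyte RNA stays possible in both sorts, but the shares per marker argue against it as the whole cause of the Cd74 excess. RNA of dendritic cells was not tested. Sex or another difference between the animals cannot be separated from disease, since Xist was 132-fold higher in EAE microglia-like cells of TRAIL+ and 108-fold higher in TRAIL-. Disease itself, through interferon gamma from infiltrating T cells, could give the same direction, and the test of monocyte RNA at 1.42% leaves it open.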

How the results depend on the processing

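All alternatives for microglia-like cells, including sums over every cell of the class and without the immune-gene cluster (cluster 4), were chosen only after the data were seen. Those for all kept barcodes were planned. The cause of a move was not tested unless stated.

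A list value was called moved when its median shifted by at least 1.5-fold, and a gene value or class share when it left its interval. A changed sign was called reversed where the list median was at least 1.5-fold or the gene's interval was clear of 1. Over all kept barcodes, 59 of 1232 list values moved and 3 reversed, and 66 of 718 gene values moved and 4 reversed. In microglia-like cells 31 of 1280 list values moved and 1 reversed, and 68 of 1056 gene values moved and 2 reversed. Of these, 46 moved and 2 reversed without cluster 4 alone, against 40 that stayed. Most named microglia-like ratios thus changed when that cluster was left out, in sums of fewer cells. Of 216 class shares 23 moved, and a share has no sign to reverse.

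The number of genes at least 2-fold apart followed the expression floor by construction. At 20 CPM and 100 CPM it was 2028 and 574 for TRAIL+ against TRAIL- in EAE, 2650 and 772 in naive, 405 and 85 for EAE against naive in TRAIL+, and 923 and 254 in TRAIL-. In microglia-like cells it was 387 and 11, 296 and 2, 222 and 42, and 1319 and 224 in the same order. From the mean of the cells' CPM it was 323 for EAE against naive in TRAIL-, and in microglia-like cells 114 for TRAIL+ against TRAIL- in EAE and 66 in naive. Without cluster 4 it was 293 for TRAIL+ against TRAIL- in EAE microglia-like cells, where 107 TRAIL- cells remained, and 45 for EAE against naive TRAIL+.

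Reversed signs came from smaller sets of cells in all but 1 case, and those of single genes rest on few UMIs. In naive astrocyte-like cells alone the TRAIL+ against TRAIL- log2 ratio was 0.31 for Atp13a5 (3 UMIs against 1), 0.31 for Depp1 (0 against 1), -0.86 for Hcls1 (4 against 0) and -0.54 for Lag3 (5 against 0), where the floor of 3 counts stands for each 0 and sets the sign, and the medians were 0.44 for cholesterol synthesis and 0.33 for glycolysis; the class held 34 and 136 cells. EAE comparisons in astrocyte-like cells were not run, with 3 and 8 cells. The neutrophil marker median for EAE against naive in TRAIL- was 0.12 from the mean of the cells' CPM. Without cluster 4, microglia-like Tnfsf10 was 0.70 (-1.28 to 3.81) for TRAIL+ against TRAIL- in EAE, on 30 against 2 UMIs. For EAE against naive in TRAIL-, H2-Ab1 was then -0.31, with 1 UMI against the floor, which shows no lower level in EAE, and the extracellular matrix list was -0.31.

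Class shares depended most on depth. At 1000 UMIs or more, naive TRAIL- held 2.30% astrocyte-like, 25.2% microglia-like, 41.8% endothelial-like, 12.02% pericyte, 1.70% monocyte or macrophage, 6.61% oligodendrocyte, 7.62% choroid plexus and 2.51% fibroblast barcodes. Naive TRAIL+ held 5.10% astrocyte-like, 87.4% microglia-like, 1.61% endothelial-like and 0.344% pericyte barcodes. EAE TRAIL- held 0% astrocyte-like, 24.1% microglia-like, 27.9% endothelial-like, 21.6% pericyte, 19.0% monocyte or macrophage and 3.23% oligodendrocyte barcodes. With at most 10% mitochondrial counts, the share was 5.13% for astrocyte-like in naive TRAIL+, 26.7% for pericyte and 1.35% for oligodendrocyte in EAE TRAIL-, and 0.0575% for oligodendrocyte in EAE TRAIL+. At Leiden resolution 2, microglia-like barcodes were 86.9% of EAE TRAIL+.

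Shares of cells with a UMI depend on depth by construction. Without thinning they were, in naive TRAIL-, naive TRAIL+, EAE TRAIL- and EAE TRAIL+, 4.81%, 0.541%, 2.99% and 2.05% for Tnfsf10 and 32.4%, 56.9%, 43.8% and 57.1% for Lamp1. Thinned to 1000 UMIs, which left out 1224, 478, 586 and 243 cells, Lamp1 was at 33.4%, 46.6%, 37.2% and 42.5%, and Tnfsf10 at 5.30% in naive TRAIL- and 0.402% in naive TRAIL+. Thus Lamp1 shares in EAE were higher in TRAIL+ without thinning but near equal, at 23.8% and 24.5%, at 500 UMIs per cell.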

Other observations

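The comparisons in this part were chosen only after the cell classes were seen. Monocyte or macrophage barcodes in EAE differed between the fractions, with 156 cells in TRAIL+ and 229 in TRAIL-. The monocyte-attracting chemokine genes Ccl12, Ccl8 and Ccl7 were 18.7-fold (9.85 to 39.9), 7.25-fold and 6.71-fold higher in TRAIL+, as were the adhesion gene Vcam1 at 7.19-fold, Slco2b1 at 6.53-fold and Egr1 at 5.07-fold. Lower in TRAIL+ were Ccr7, Ccl22 and Ccl17, which migratory dendritic cells express, with Ccr7 at least 15.8-fold, Ccl22 at least 15.5-fold and Ccl17 66.0-fold (11.6 to 2640), and so were the blood monocyte genes Plac8 at 4.68-fold and Chil3 at 3.11-fold. Interferon-induced Gbp2 and Cxcl9 were 4.05- and 3.77-fold lower, and type I interferon-stimulated genes were lower in 14 of 21. Cd74 was 2.01-fold higher. Microglia markers were higher in 13 of 14 in the TRAIL+ cells, with C1qb at 4.22-fold, so the mix of cells inside the class differed as well. A macrophage cluster led by Pf4, Mrc1 and Ccl7 held 17 of the TRAIL+ cells and 1 of the TRAIL- cells, and the other cluster, led by Chil3 and Plac8, held 139 and 228.

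Astrocyte-like cells were compared only between naive TRAIL+ and naive TRAIL-, with 136 and 34 cells. The 34 cells held 79949 UMIs, under the planned minimum of 50 cells and 100000 UMIs. Immediate early genes were lower in 16 of 20 in TRAIL+, with Fos 6.57-fold (5.44 to 7.97), Ccn1 14.5-fold, Maff 9.89-fold, Klf2 8.46-fold, Btg2 5.70-fold and Socs3 5.67-fold lower. NF-kB targets were higher in 7 of 10, including Tnf at 13.4-fold and Tnfaip3 at 10.2-fold, next to Ccl4 at 27.4-fold (9.25 to 134), Cd83 at 15.02-fold, Ctss at 8.20-fold and Cst3 at 3.79-fold. Microglia markers were higher in 13 of 14 in the same cells, C1qc by 7.74-fold, while astrocyte markers lay between in 16 of 25.

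Vascular and other classes of the TRAIL- libraries were compared between EAE and naive mice. Endothelial-like cells, 496 in EAE and 1142 in naive, had higher Scgb3a1 at 9.76-fold, Map3k6 at 7.83-fold, the class I gene H2-Q7 at 6.33-fold, the cholesterol hydroxylase gene Ch25h at 6.23-fold and Galnt15 at 4.82-fold, and the leukocyte adhesion gene Icam1 at 2.96-fold. Dok4, Nemf, Rflnb and the Wnt regulator gene Nkd1 were 5.66-, 3.799-, 2.83- and 2.71-fold lower. Pericyte-like cells, 460 and 498, had 70.0-fold (19.1 to 583) higher Cxcl10 and 17.2-fold (7.11 to 54.0) higher Cxcl1, both leukocyte chemokine genes, and 18 of 21 type I interferon-stimulated genes were higher, with Isg15 at 9.14-fold and Iigp1 at 7.99-fold. Lgals3bp was 7.09-fold higher and Gadd45a 4.50-fold lower. At a limit of 10% mitochondrial counts the pericyte share of EAE TRAIL- fell from 29.2% to 26.7%, so RNA quality is a limit here. Choroid plexus-like cells, 40 and 87, had higher Cd74 at 48.6-fold (12.7 to 413), Gpx3 at 60.2-fold, A2m at 10.8-fold and B2m at 3.93-fold, with monocyte markers higher in 5 of 5. Oligodendrocyte-like cells, 35 and 75, had higher B2m at 37.4-fold (21.1 to 73.3), H2-D1 at 32.8-fold, H2-T23 at least 49.4-fold, Igtp at least 32.2-fold and the serpin gene Serpina3n at 17.6-fold, and 9 of 10 MHC class I genes were higher. At a limit of 10% mitochondrial counts 19 of the EAE and 70 of the naive cells remained, so RNA quality differed between these cells too. S100b and Dennd5a were 4.62- and 7.97-fold lower. The Xist and Ddx3y differences between EAE and naive animals apply to each of these classes.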
